A study of Danio rerio with 10 samples.

How the data were processed

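The data were 10 assembled transcriptomes of zebrafish, 1 for each of 5 tissues on 2 platforms. Per the labels' protocols, the AB line was used, organs came from male adults, larvae and tails were pooled at 4 days after fertilization, total RNA was extracted from all tissues in the same way, Illumina libraries used 500 ng of total RNA, bead-based mRNA capture and 15 PCR cycles in a stranded protocol, and PacBio libraries used 300 ng in an Iso-Seq Express protocol. The labels name no batch, animal or replicate, so the number of fish behind each library was not analysed here.

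Each deposited assembly lists transcripts and exons with their positions and, for each transcript, a mean per-base coverage, an FPKM and a TPM that the authors' assembler computed. Per the file headers, assembly used StringTie version 2.1.5 with a GRCz11 guide annotation on 1 merged alignment per library, with no long-read option and no strandedness option. HISAT2, minimap2 and bedtools are named per the submitters' processing notes, without role or version there. Read trimming, filters and whether the aligned PacBio sequences were single reads or clustered consensus sequences are not given in the sources used here. Deposited TPM values summed to between 993065 and 998095 per library, and the ratio of deposited coverage to FPKM was 1 constant per library, which equals the aligned bases that FPKM was scaled to. This gave 60.9 (larvae), 66.1 (tail), 111 (muscle), 111 (brain) and 121 Gb (liver) for Illumina, and 46.0, 46.0, 194, 69.5 and 46.2 Mb for PacBio. The values are not counts, so no count model was used. At these PacBio depths many values rest on about 1 aligned sequence (median spliced coverage 0.922 to 2.38, against 11.7 to 25.6 on Illumina), a PacBio value of 0 is weak evidence of absence, and PacBio folds are coarse. In 2 Illumina libraries 1 transcript each had a negative coverage and was kept at its listed TPM.

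The guide annotation held gene-level entries beside transcripts, so that gene bodies occur in the assemblies as single-exon transcripts. Entries were therefore sorted as matched to an annotated transcript, matched to a gene body, or new. No reference genome or annotation of this build was used here. An annotated intron chain was taken as the chain of any transcript that the assembler matched to the guide annotation in any of the 10 libraries, which departs from the planned comparison with the full annotation and counts unassembled annotated chains as absent. Annotated transcripts were assigned to the 26818 gene bodies by containment (33838), shared splice sites (5181) or the position of their start (938), which placed 39957 of 42413 (94.2%). Of 23346 gene bodies with such transcripts, 4157 (17.8%) ended before the last of them, so gene bodies were not always whole. New transcripts were assigned by shared splice sites or by the gene body on the same strand that covered most of their span, if at least 0.5 of it, which placed 26.4% to 38.4% of them on Illumina and 64.8% to 73.6% on PacBio. Symbols were found for 24869 gene bodies (92.7%), many in the form of the human gene, and a symbol can cover several zebrafish genes. Gene abundance was the summed TPM of assigned transcripts, and a gene-body entry counted only for genes with no spliced transcript in any library.

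Platforms were compared within tissues for the number of transcripts, the share with a single exon, the median length of spliced transcripts, the number of distinct introns and the share of annotated intron chains. Each used a two-sided exact paired sign-flip permutation test over 5 tissues, whose smallest p is 0.0625, and Benjamini-Hochberg adjustment over the 5 measures. The tissues are different kinds of sample, so this p measures only how alike the platform difference was across them. The planned comparison of open reading frames needs the genome sequence and was not run. A tissue-enriched gene had at least 10 TPM and was at least 8-fold above each other tissue on the log2(TPM + 1) scale on both platforms, and tail and whole larvae were compared with 4-fold and 10 TPM in the higher sample. Dominant isoforms were compared for 6 pairs of tissues with at least 10 TPM. The overlap of independent lists is the product of the 2 platforms' counts of calls among the 10191 genes with 10 TPM somewhere on both platforms, over 10191. Folds against low values are understated by the pseudocount of 1.

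The 22 gene lists (skeletal muscle, slow muscle, cardiac muscle, neuron, glia, pituitary hormones, liver, vitellogenins, exocrine pancreas, intestine, epidermis, fin fold and skeletal matrix, notochord, retina and lens, adult globins, embryonic and larval globins, erythroid, leukocyte, pigment cell, proliferation, cytosolic ribosome and giant genes) held 436 names. Of these, 321 matched a symbol, 83 a symbol without its paralogue suffix, which also brings in paralogues, and 32 none. For each tissue and platform the median over members of the log2 ratio to the mean of the other 4 tissues was placed among 10000 random lists of the same size, matched in 20 bins of mean abundance. The lists, tests, thresholds, most of the other settings tried and naming rule were set before the data were examined. The germ cell and testis list and the immediate early list were written after the enriched genes were seen.

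Named genes followed fixed rules, which leave out clone and locus names. Per tissue they were the 6 enriched genes with the largest smaller-of-both-platforms fold above the next tissue, and for tail against larvae the 8 per direction. For platforms they were the 8 per direction with the highest mean abundance on a single platform, and for isoforms the 6 per pair with the highest smallest abundance. From each list they were up to 4 members with the highest mean abundance over the libraries of its highest tissue, and members named for going the other way. Some genes that these rules select are not reported here. Genes named outside these rules, such as SYCP1, PIWIL1 and MT-CO1, were chosen after their values were seen.

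Alternatives were TPM of 1 or more, a pseudocount of 0.1, another fold or abundance minimum, Illumina alone, values rescaled by trimmed mean of M values (TMM, trimming 30% of log ratios and 5% of mean abundances), introns matched within 5 nt, and leaving out each tissue in turn. Added after the data were seen were gene-body entries left out or counted for every gene, larvae and tail as 1 group, counts without germ-cell and pancreas genes, and the immediate early list under TMM scaling. The selection rules were tested on simulated data of 6618 genes with 200 changed and log2 noise of SD 0.3 on Illumina and 0.6 on PacBio. For the tissue-enriched rule 26.5% of genes changed 16-fold, 64.5% of those changed 32-fold and 87% of those changed 64-fold were recovered, and for the tail rule 81% at 8-fold, 97% at 16-fold and 99% at 32-fold, with 0 false calls in each. The simulated values held no zeros and no sampling of single sequences, unlike the PacBio data. The 0 false calls therefore do not measure the error of these rules on the real libraries. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.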

Results

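RNA from 5 zebrafish (Danio rerio, AB line) sources was sequenced on 2 platforms, which gave 10 libraries. The sources were whole larvae at 4 days after fertilization, tails dissected from larvae and pooled, and muscle, brain and liver of adult males. Each source was sequenced with Illumina short reads from poly(A)-selected stranded libraries and with PacBio Iso-Seq, in which long cDNA molecules are read individually. The study set transcript and protein data side by side to build protein databases for zebrafish samples. The proteomics part was not analysed here. There was 1 library for each tissue and platform, so no difference between tissues had a replicate check, and the second platform was the only repeat. The deposited assemblies listed 96091 to 142782 transcripts per Illumina library and 14414 to 22962 per PacBio library. Coverage and FPKM values gave aligned totals of 60.9 to 121 Gb on Illumina and 46.0 to 194 Mb on PacBio. The median coverage of a spliced transcript was 11.7 to 25.6 on Illumina and 0.922 to 2.38 on PacBio, so that many PacBio values rested on about 1 aligned sequence. Whether those were single reads or clustered consensus sequences is not given in the sources used here, and if they were clustered, PacBio TPM would count distinct sequences and would not measure abundance. Spliced PacBio transcripts had a median of 30.6 TPM in muscle, at coverage 2.38, and of 67.3 TPM in tail, at 0.922. The minimum of 10 TPM used below thus lay under a coverage of 1, and 1 sequence against none could pass the PacBio rules. The assemblies give no read counts, and counting intervals could not be set. Abundances below are TPM summed per gene, folds are on the log2(TPM + 1) scale, and positions are on GRCz11.

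Whole larvae and the 3 adult tissues each had tissue-enriched genes on both platforms. With TPM of at least 10 and at least 8-fold above every other tissue on both platforms, 211 genes were enriched in liver, 122 in whole larvae, 74 in brain, 57 in muscle and 0 in larval tail. Whole larvae include the tail, which limits how far a tail gene can stand above them. In liver the leading named genes included hpxa, a haemopexin that binds haem in plasma, at 2157 TPM on Illumina and 778 on PacBio, and serpina7, of the serpin family of plasma proteins, at 1533 and 1746 TPM. The liver gene rnasel2, of the ribonuclease family (ENSDARG00000043196, chromosome 22, 6293563 to 6294749), reached 3147 and 912 TPM and lay 9.45 and 9.83 log2 units above the next tissue. The others named were cbln8, ccl39a.10, a chemokine, and spp2, a secreted phosphoprotein. In whole larvae the leading genes were of the eye. OPN1SW, a short-wavelength cone opsin (ENSDARG00000045677, chromosome 4, 13577665 to 13580348), stood at 1644 and 581 TPM, and the lens crystallins crybb1l1, crybb1l2, CRYGN, CRYBA2 and CRYBB1 at 625 to 2461 TPM on Illumina and 295 to 550 TPM on PacBio. All 6 were listed at 0 in the other 4 PacBio libraries.

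In brain the 6 leading genes included NPAS4, a neuronal activity-induced transcription factor (ENSDARG00000055752, chromosome 14, 30636955 to 30642819), at 249 TPM on Illumina and 106 on PacBio, cbln12, a cerebellin of the synaptic organizer family, at 467 and 191 TPM, and egr2a, an early-response zinc-finger transcription factor, at 66.8 and 166 TPM. The others named were ankrd67, rusc2 and smu1b. The brain genes lay 5.22 to 6.20 log2 units above the next tissue on Illumina. The smaller of the 2 platforms' values was 5.22 to 5.88, and 3.59 to 5.38 under trimmed-mean (TMM) scaling. In muscle the leading gene was TNNI2, the fast-fibre inhibitory troponin (ENSDARG00000013752, chromosome 25, 31264155 to 31275944), at 3515 and 372 TPM, 8.97 and 8.54 log2 units above the next tissue. The other muscle genes were nnt2, gstk4, tnni4b.1, a further troponin I, PPP1R27, a regulator of a protein phosphatase, and myhz1.1l, a fast myosin heavy chain at 2016 and 7883 TPM. Myosin heavy chains, crystallins and globins have near-identical paralogues, and abundance split among them is uncertain. The listing of myhz2 at 0 in the Illumina muscle library and at 9103 TPM in the PacBio one is an example chosen after its values were seen.

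Genes of other organs were present in the adult samples. The muscle libraries held transcripts of germ cells, such as SYCP1 of the meiotic synaptonemal complex at 48.7 TPM on PacBio and PIWIL1 of the piRNA pathway at 40.8 TPM on Illumina, and of the exocrine pancreas, such as trypsin prss1 at 86.4 TPM on Illumina. The liver held prss1 at 886 TPM. Without the germ-cell and pancreas genes the muscle count was 48, and without the pancreas genes the liver count was 210.

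The counts depended on the scaling of the Illumina values. The top 10 genes took 14.3% of assigned TPM in larvae and 40.3% in muscle, and TMM scaling moved Illumina log2 values by -0.75 in larvae, -0.18 in tail, 0.95 in muscle, -1.08 in brain and 1.06 in liver. On PacBio it moved them by 0.05, -0.06, 0.33, -0.10 and -0.22. Under it 287 genes were enriched in liver, 170 in muscle, 105 in larvae and 35 in brain, so that larvae came after muscle. On Illumina alone the counts were 297, 170, 195, 94 and 3 in the order liver, larvae, brain, muscle and tail, and on PacBio alone 585, 756, 1080, 927 and 604. Among the 10191 genes that reached 10 TPM on both platforms, these calls numbered 281, 138, 154, 69 and 2 on Illumina and 397, 386, 735, 389 and 274 on PacBio. Independent lists of those sizes would share 10.9, 5.23, 11.1, 2.63 and 0.0538 genes. With whole larvae and tail joined as 1 group against the adult tissues, 134 genes were enriched, 243 on Illumina alone.

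Many of the gene lists fixed beforehand, though not all, followed the anatomy of the samples. Of 22 lists, 17 were at or above the 97.5th percentile of 10000 abundance-matched random lists on both platforms in the tissue with the highest sum of the 2 platforms' medians. For 11 of the 17 that tissue had the highest median on each platform, and for 6 another tissue was higher on a platform. The percentile describes these libraries only. The tissue was chosen by the same medians, so the percentile is a lower bar than for a tissue fixed beforehand. Among the 17 were the exocrine pancreas list in liver and the leukocyte and giant gene lists in muscle, the last with an Illumina median of -0.02. The liver list, of plasma proteins and other hepatocyte products, had a median of 7.44 log2 units above the mean of the other tissues on Illumina and 7.15 on PacBio, with 46 of 47 and 45 of 46 members higher. Its most abundant members were fabp10a, the liver fatty acid-binding protein, at 52040 TPM on Illumina but 928 on PacBio, and the apolipoproteins apoc1, apoa2 and apoa1b, at 26565 to 40546 TPM on Illumina and 281 to 5258 on PacBio. The neuron list stood at 5.45 and 5.06 in brain, with 42 of 43 and 39 of 42 members higher. It was led by SNAP25, a synaptic vesicle fusion protein (2906 and 1929 TPM), the synucleins SNCG and sncb, and STMN1, a microtubule regulator. The glia list stood at 4.40 and 4.43, led by the myelin genes mbpa (10156 and 5487 TPM) and plp1b, and by FABP7 of radial glia.

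The skeletal muscle list separated the adult muscle and both larval samples from brain and liver. It stood at 4.27 and 5.24 in adult muscle, 3.73 and 3.15 in larvae and 4.03 and 3.56 in tail, but at -5.14 and -4.52 in brain. In adult muscle it was led by the calcium buffers pvalb4 (46200 TPM on Illumina, 1201 on PacBio) and pvalb3 (27984 and 953), and by the creatine kinases ckmb and ckma. The parvalbumin pvalb1 went the other way between ages, at 7509 TPM in adult muscle, 15209 in larvae and 32528 in tail on Illumina. On PacBio pvalb1 was at 490, 89.4 and 315 TPM. The slow muscle list was highest in muscle (2.58 and 5.06), against 1.65 and -0.22 in larvae and 0.94 and -1.53 in tail, with smyhc2, a slow myosin, at 455 and 1582 TPM, TNNC1, tnni1c and smyhc1. Its member smyhc1 had more Illumina abundance in tail (1734 TPM) than in muscle (36.1 TPM). The giant gene list, which holds the longest transcripts, stood at -0.02 in muscle on Illumina (0.64 in larvae and 0.51 in brain) and 3.46 on PacBio, and the Illumina sign turned under TMM scaling. It was led by TTN, the sarcomere spring titin (gene ENSDARG00000028213 at 152 and 905 TPM, gene ENSDARG00000000563 at 103 and 821), NEB (237 and 520) and RYR1 (83.0 and 446). The muscle PacBio library was also the deepest, with 194 aligned Mb against 46.0 to 69.5 in the others. The part of depth in the high PacBio median of this list was not tested.

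Whole larvae were marked by genes of eye and gut, and both larval samples by genes of skin and skeleton. The retina and lens list stood at 6.13 and 7.46 in whole larvae, with 35 of 35 and 28 of 30 members higher, and at -2.05 and -1.93 in tail, led by CRYBB1, cryba1b and opn1lw2. The epidermis list stood at 4.39 and 3.91 in larvae and 4.68 and 3.92 in tail, led by the keratins krt4 (6554 and 1583 TPM in tail), cyt1, krt5 and krt91. In tail the fin fold and skeletal matrix list stood at 3.18 and 6.68 (3.19 in larvae on Illumina), led by the type I collagen genes col1a1a (1911 and 3770 TPM), COL1A2 and COL1A1, and by and2, an actinodin of the fin fold. The notochord list stood at 2.80 and 5.48 in tail, led by 2 collagens, COL2A1 and col9a1b, with COL9A2. The pigment cell list stood at 2.84 and 5.16 in larvae, with pmela, TYRP1, DCT and pnp4a, and the proliferation list at 2.47 and 3.51 (3.71 in tail on PacBio), with tuba8l4, PCNA and STMN1 (2 genes). The cardiac list stood at 2.90 in larvae on Illumina, with 13 of 13 members higher, and at 2.22 on PacBio with 3 of 6 higher, at the 91.8th percentile. The natriuretic peptide nppa, the light chains cmlc1 and MYL7, and MYH6 led it. The intestine list stood at 3.95 and 4.04 in larvae and -0.16 and -0.59 in tail, led by apoa4b.1, FABP2, chia.2 and RBP2. Of these, apoa4b.1 was higher in liver (1557 TPM) than in larvae (703 TPM) on Illumina.

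Blood and immune genes differed between larval and adult samples. The adult globin list had 2 members assembled. The alpha globin hbaa1 stood at 366, 663 and 521 TPM in muscle, brain and liver on Illumina, against 0.44 and 0.46 TPM in larvae and tail, and hbaa2 was listed at 0 in both larval samples. The list stood at 3.34 and 3.28 in muscle, at the 99.5th and 96.4th percentiles. The embryonic and larval globin list stood at 6.02 and 5.62 in tail, led by hbae3 (1369 TPM on Illumina), hbae1.1, hbae1.2 and hbae1.3. The leukocyte list stood at -0.65 and -2.87 in larvae, below all random lists on both platforms, and at 0.19 and 3.01 in muscle. It was higher in brain on Illumina (1.13) and in liver on PacBio (3.09). Its member b2m, the light chain of MHC class I, had 3.28 TPM in larvae and 2.64 in tail against 250, 174 and 329 TPM in muscle, brain and liver. The invariant chain cd74a, cd74b and lyz, a lysozyme, followed. The other erythroid genes, led by UROD, nt5c2l1, SLC4A1 and cahz, stood at 1.06 and 0.58 in tail, and only the Illumina median was high among random lists (99.8th and 67.8th percentiles).

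The exocrine pancreas list was high in both larvae (3.66 and 3.37) and liver (3.64 and 5.65), led in liver by prss1, prss59.1, CELA1 and ctrb.1. In muscle it stood at 0.50 and 0.12. The cytosolic ribosome list, led by RPS2, rpl32, RPL19 and RPLP0, stood at 0.84 and 0.79 in liver (2.16 and 0.52 under TMM scaling) and at 0.92 and -0.27 in larvae. In muscle it stood at -1.13 on Illumina and 0.73 on PacBio, and the Illumina value was 0.05 under TMM scaling. The pituitary list was low. Its Illumina median was 0.26 in larvae, at the 98.6th percentile, with gh1 at 3.96 TPM, POMC at 2.66, CGA at 1.12 and smtlb at 0.24, and 1 member was assembled on PacBio. The vitellogenin list stood at 0.01 in larvae on Illumina with no member on PacBio, the sign turned under TMM scaling, and vtg7, ESR1, vtg1 and vtg2 were each under 1 TPM there. The adult fish were males.

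**Figure D1:**
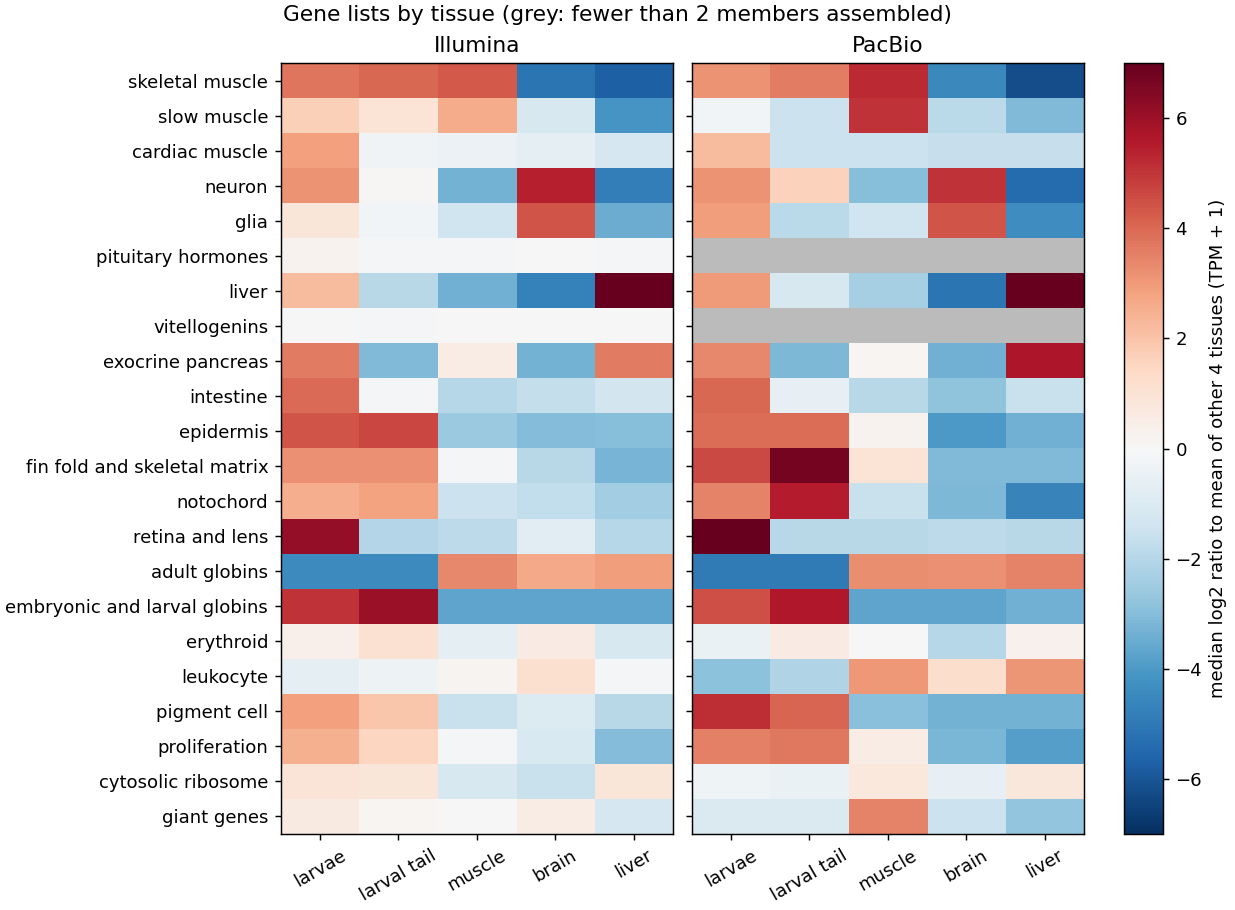
Median log2 ratio of each of the 22 gene lists in a tissue to the mean of the other 4 tissues, on the log2(TPM + 1) scale, for Illumina (left) and PacBio (right). Red marks lists above the other tissues, blue lists below them, and grey fewer than 2 assembled members. The liver list reached 7.44 and 7.15 in liver and the retina and lens list 6.13 and 7.46 in whole larvae. Under TMM scaling the signs of 17 of the 110 Illumina medians turned, among them the ribosome list in larvae and muscle and the giant gene list in larvae, muscle and brain.

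The larval tail was compared with the whole larva of which it is a part. At 4-fold or more on both platforms and TPM of at least 10 in the higher sample, 499 genes were higher in whole larvae and 9 in tail. Tail transcripts also count in whole larvae, which limits folds in favour of tail but not those in favour of larvae. The 2 counts therefore do not compare how distinct the samples were. OPN1SW, crybb1l1, crybb1l2, CRYGN and CRYBA2, named above, were among the leading genes higher in whole larvae, with gnb3b, a cone transducin subunit (434 against 0 TPM on Illumina), and MATN1, a cartilage matrix protein (320 against 0.0432 TPM). In tail HOXB13, a posterior homeobox gene (ENSDARG00000056015, chromosome 3, 23654233 to 23655834), stood at 33.8 against 7.21 TPM on Illumina, 2.09 log2 units higher, and at 62.0 TPM on PacBio where larvae were listed at 0. That PacBio value is a coverage below 1, since 67.3 TPM in tail went with a coverage of 0.922, so it is a weak repeat. The matrix genes were FMOD, a small collagen-binding proteoglycan (31.2 against 4.57 TPM), vcanb, a versican (86.3 against 17.7 TPM), and EGFL6, a basement membrane protein (54.3 against 2.77 TPM). CAPN3, a muscle calpain, stood at 21.7 against 1.42 TPM, and AVEN, ST7 and ACOT13 made up the 8 named genes.

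Among the 10191 genes with 10 TPM on both platforms, 801 were called higher in whole larvae on Illumina and 1866 on PacBio, and 33 and 1065 higher in tail. Independent lists of those sizes would share 147 and 3.45 genes. Of the 1720 genes called higher in tail on PacBio alone, 1061 had the opposite sign on Illumina, where 39 were called. TMM scaling gave 298 genes higher in larvae and 23 in tail.

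For a small share of genes the most abundant spliced isoform differed between the libraries of 2 tissues. A gene was compared where each of 2 tissues had the same most abundant intron chain on both platforms, at 10 TPM or more. PacBio had a mean of 1.25 ± 0.0631 spliced chains per gene, so its most abundant chain was often the only one. The number of differences to expect without a tissue effect was not computed. The leading isoform differed for 61 of 1662 genes between muscle and brain, 56 of 3095 between larvae and brain, 44 of 1564 between brain and liver, 41 of 1785 between larvae and muscle, 36 of 1333 between muscle and liver, and 31 of 1736 between larvae and liver. ALDOA, a glycolytic aldolase (chromosome 3, 39566999 to 39577052), used an initial intron from 39567077 to 39568786 in muscle and from 39568408 to 39568786 in brain, with leading isoforms at 4466 and 536 TPM on Illumina. SLC25A3, the mitochondrial phosphate carrier (chromosome 25, 3306620 to 3321365), differed in 2 introns between liver and each of larvae, muscle and brain. In liver an intron ran from 3307204 to 3312202 and in the other tissues from 3307204 to 3310340, so that 1 internal exon was exchanged for another. The liver isoform stood at 381 TPM and the muscle one at 979 TPM on Illumina.

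The parvalbumin pvalb7 had another first exon in muscle (first intron 29186661 to 29191090 of chromosome 22, minus strand) than in larvae and brain (29186661 to 29242067). CAPZB, an actin-capping subunit, had 9 introns in larvae and muscle and 8 in brain, with an intron from 406160 to 407531 of chromosome 22 in the former and from 406160 to 410453 in the latter, which lacks an internal exon. The cytoskeletal regulators PFN2 and CDC42 had different last introns in larvae and brain. That of PFN2 (chromosome 2) ran from 10148574 to 10149901 in larvae and from 10148574 to 10149578 in brain, and that of CDC42 (chromosome 11) from 39139070 to 39146812 in larvae and from 39139070 to 39141319 in brain. EEF1D, a translation elongation factor subunit, had 6 introns in larvae and liver and 7 in muscle. DDX5, an RNA helicase, had 11 introns in larvae and muscle and 12 in liver, with 1 further intron from 25271172 to 25272019 of chromosome 3. APP, the amyloid precursor, had 15 introns in larvae and 16 in liver. Other leading genes were BHMT, MYOM1, TMED2 and HSDL2 between larvae and muscle, CKMT1B, gpx4a and dap1b between larvae and brain, and NDFIP1, AGPAT3 and kgd4 between larvae and liver. They were naca, NDUFB2 and chchd6b between muscle and brain, rtn4a between muscle and liver, and fkbp1aa and ZFYVE21 between brain and liver. Differences on a single platform were more frequent, at 14.3% to 18.5% of genes on Illumina and 12.9% to 15.5% on PacBio, against 1.79% to 3.67% on both. At 50 TPM or more, 3 to 15 genes per pair differed.

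Illumina and PacBio assemblies were compared within each tissue, the contrast that the design repeats. Illumina gave 115751 ± 17626 transcripts (SD, n = 5 tissues) and PacBio 19891 ± 3378, and distinct introns numbered 226274 ± 29026 and 61694 ± 11499. Of the distinct intron chains, 48.7% ± 2.91 on Illumina and 82.2% ± 5.78 on PacBio were those of a transcript matched to the guide annotation. The median spliced length was 1875 ± 101 nt on Illumina and 1783 ± 118 nt on PacBio. These 4 differences had the same sign in 5 of 5 tissues (mean differences -95860 transcripts, -164580 introns, 33.5 ± 3.69 percentage points and -91.8 ± 57.4 nt), each with p = 0.0625 (two-sided exact paired sign-flip permutation test, n = 5; 0.0781 after Benjamini-Hochberg adjustment over 5 measures). That p is the smallest 32 sign flips allow, so p under 0.05 was out of reach. Single-exon entries made up 47.4% ± 4.90 of Illumina and 48.6% ± 1.61 of PacBio transcripts, a difference of 1.14 ± 3.85 percentage points that was positive in 3 of 5 tissues (exact sign-flip permutation p = 0.5625, adjusted 0.5625, n = 5). Gene bodies written as single exons were 21.9% ± 2.63 of Illumina and 46.6% ± 1.64 of PacBio entries, and without them the shares were 32.7% ± 6.75 and 3.62% ± 0.214, a difference of -29.0. At TPM of 1 or more, gene bodies included, they were 17.2% ± 3.14 and 30.9% ± 7.15, a difference of 13.7. At the same minimum without gene bodies they were 15.2% ± 2.99 and 2.71% ± 0.195.

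**Figure D2:**
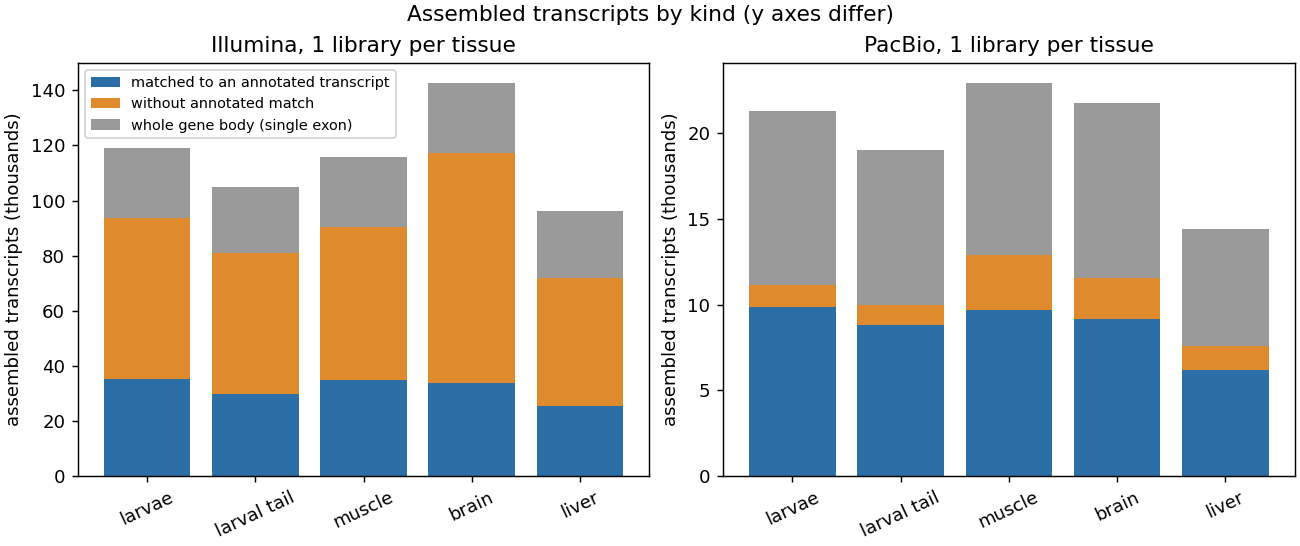
Number of assembled transcripts (in units of 1000) per library, Illumina left and PacBio right with different y axes, by whether the assembler matched them to an annotated transcript, to no annotated transcript, or to a gene body written as a single exon. Each bar is 1 library. Brain had the most on Illumina (142782) and muscle on PacBio (22962).

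Splice sites seen on PacBio, most of them annotated, were nearly all seen on Illumina. In the same tissue, 96.7% ± 1.25 of PacBio introns were among the Illumina introns (SD, n = 5) and 26.2% ± 2.51 of Illumina introns were among the PacBio ones. Introns of transcripts matched to the guide annotation made up 93.4% ± 2.38 of PacBio introns. They made up 17.6% to 33.1% of the PacBio introns not seen on Illumina, so introns outside the annotation were shared less often. Both platforms were assembled with a guide annotation, and its part in the sharing was not tested. Whole PacBio intron chains were shared in 84.2% ± 4.27, but PacBio chains without an annotated match in 24.6% ± 1.82. Recovery on PacBio depended on length. Of annotated spliced transcripts with Illumina TPM of at least 10, 86.9% ± 4.59 of those from 1000 to 2000 nt were assembled on PacBio, 75.7% ± 7.81 of those from 3000 to 4000 nt, 43.1% ± 7.62 of those from 6000 to 8000 nt, and 22.6% ± 2.65 of those of 8000 nt or longer. Below 500 nt the share was 70.8% ± 9.76.

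**Figure D3:**
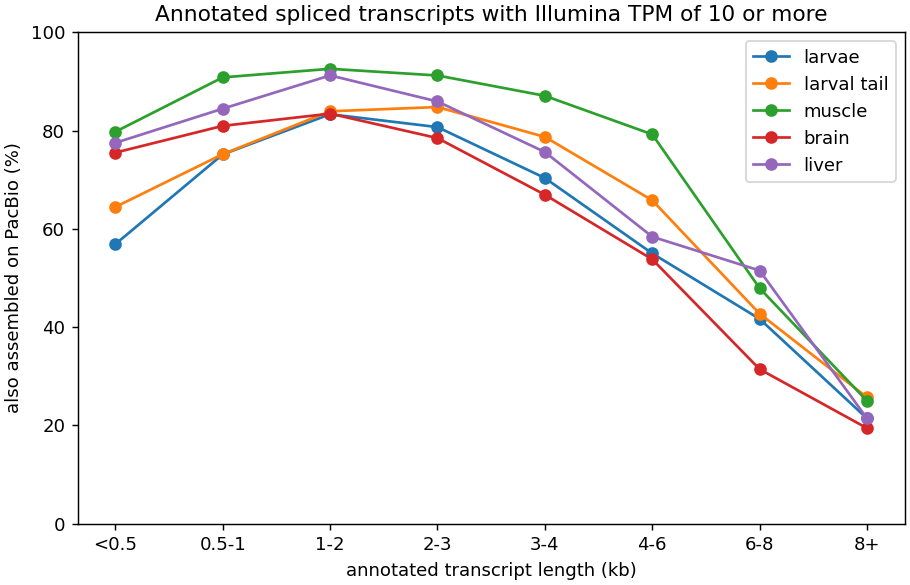
Percent of annotated spliced transcripts with Illumina TPM of at least 10 that were also assembled on PacBio in the same tissue, by transcript length in kb, with 1 line per tissue. All 5 lines fall beyond 3 kb, to 19.4% to 25.7% at 8 kb or longer.

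Genes found on a single platform were mostly Illumina genes. Of genes with summed abundance, 9957 were on Illumina only, 172 of them with a mean of 10 TPM or more. On PacBio only there were 16, 2 of them with such a mean. The leading Illumina-only genes were rn7sl1, the RNA of the signal recognition particle (mean 76.1 TPM), akap7, a kinase anchoring protein (56.4 TPM), NR1D1, a nuclear receptor of the circadian clock (47.3 TPM), and mapta, a tau (42.6 TPM), followed by hnrnpr, CENPV, a 5S_rRNA gene and col4a5, a basement membrane collagen. The PacBio-only genes at 10 TPM or more are left out by the naming rule. The named PacBio-only genes, led by 5S_rRNA (mean 8.58 TPM), DCTPP1, 5_8S_rRNA and the microRNA genes dre-mir-30b and MIR144, were low. The other 3 of the 8 leading ones were 5S_rRNA genes. Mitochondrial genes took 18.4% ± 7.58 of TPM on Illumina and 2.39% ± 1.65 on PacBio (SD, n = 5). MT-CO1, a subunit of cytochrome oxidase, had 62020 TPM on Illumina and 6272 on PacBio in muscle.

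Across genes assembled on both platforms, which are not independent replicates, the Spearman correlation of log2(TPM + 1) was 0.743 in muscle (8624 genes), 0.703 in liver (5595), 0.631 in brain (8333), 0.456 in larvae (8744) and 0.433 in tail (7822), with a mean of 0.593 ± 0.142 (SD, n = 5). The mean Pearson correlation was 0.609 ± 0.103. The SD of PacBio log2 values was 0.756 ± 0.131 times that of Illumina values. Over genes on either platform, with 0 where absent, that ratio was 1.49 ± 0.0821 and the Spearman correlation was 0.644 to 0.699 (mean 0.667 ± 0.0227).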

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

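The tests of carry-over, of the gene-level entries and of the recovery of long transcripts were chosen only after the results they bear on were seen. The germ-cell test and the test of low-abundance single-exon fragments were set before their outcomes were seen.

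The adult muscle libraries held transcripts of testis and pancreas, and the most abundant of a list of germ cell and testis genes, written after the enriched genes were seen, were insl3, a Leydig cell hormone, at 85.2 TPM on Illumina, SYCP1 (48.7 TPM on PacBio), PIWIL1 at 40.8, TEKT1 of sperm tails at 36.4 and gsdf of the somatic gonad at 31.9, with trypsins prss1 at 86.4 and prss59.1 at 114 TPM. Of 51 names of the list 44 were matched, with an Illumina median of 6.52 TPM in muscle against 0.168 in larvae, 0.236 in brain and 0 in liver. RNA of testis and other abdominal organs in the muscle sample is a possible explanation, since 85.7% of the list's members outside the muscle-enriched genes (30 of 35) were highest in muscle on Illumina. Carry-over of liver molecules as the whole source was excluded, since muscle held a median of 16.4% of the liver's pancreas transcripts but 0.121% of its liver transcripts, a ratio of 136, and so was carry-over from whole larvae, since muscle held a median of 19.9% of the larval pancreas transcripts (quartiles 9.95% and 34.3%) but 0.00156% of the larval retina and lens transcripts (quartiles 0% and 0.0777%), a ratio of 12730 over a value near 0. Transcription of these genes by muscle itself was not tested.

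Among all entries, those with a single exon took a nearly equal share on both platforms. At TPM of 1 or more, gene-level entries included, the PacBio share was 13.7 percentage points higher. Gene-level entries of the guide annotation, written as single exons, made up 46.6% of PacBio and 21.9% of Illumina entries. Without them the PacBio minus Illumina difference was -29.0 percentage points, a move that follows from this composition. The nearly equal share over all entries thus rests on counting them. Low-abundance fragments may add to the Illumina share, which without gene-level entries was 32.7% and at TPM of 1 or more 15.2%. On PacBio those shares were 3.62% and 2.71%. The higher PacBio share at TPM of 1 or more thus also rests on counting gene-level entries. No biological explanation was tested.

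Long transcripts were recovered less on PacBio. Loss of long molecules is a possible explanation. Among genes with Illumina TPM of 10 to 30, recovery at 6 kb or more minus that at 1 to 2 kb was -39.4 ± 5.98 percentage points (SD, n = 5). This range alone cannot show a loss whatever the abundance. Mean recovery at 6 kb or more was 45.2% there and 76.1% at TPM of 30 or more, against 84.6% and 97.1% at 1 to 2 kb. The mean difference was thus smaller for more abundant genes. The values argue against lower PacBio depth alone as the whole cause, since it predicts equal recovery at equal abundance. At TPM of 30 or more the difference was still -21.0 ± 13.9, from -36.5 to -5.31 over tissues. Abundance was matched only within these ranges, so equal abundance was approximate. Long genes at TPM of 30 or more against shorter ones at 10 to 30, a comparison that decides less, differed by -8.44 ± 6.81. In all these values a gene counted as recovered if any spliced PacBio transcript was assigned to it. With both abundance ranges pooled, which loosens the match of abundance, the difference was -37.9 ± 8.80. It is the same measure and not a separate test. Shortened transcripts that kept an intron therefore do not account for the whole loss. Those cut back to 1 exon would score as not recovered, so shortening at one end was not excluded. No biological explanation was tested.

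Among 22 groups of 5 libraries, 3 had a library far from the others, where chance flags about 1 in 20 groups, and tissues are not replicates. The muscle PacBio library had 45.8% single-exon entries against 48.9% to 49.7% in the other PacBio libraries. The liver PacBio library had 41502 distinct introns against 64119 to 69253. The muscle PacBio library had 194 aligned Mb against 46.0 to 69.5. The PacBio minus Illumina difference in single-exon share had opposite signs in 2 tissues, at -3.06 percentage points in brain and 5.99 in muscle, a difference that was not tested. New spliced chains assigned to no gene, which enter the structure counts but no gene comparison above, were found on both platforms in 380 cases. Of these, 76 were in larvae, 66 in tail, 154 in muscle, 136 in brain and 101 in liver, and 100 in 2 or more tissues. The highest on Illumina had 2 exons on chromosome 23 (16867691 to 16878611, minus strand), at 692 TPM on Illumina and 193 on PacBio in tail. Some of the 380 chains may lie in annotated genes, since 17.8% of gene bodies ended before the gene's last annotated transcript.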

How the results depend on the processing

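The alternatives that left out gene-body entries or counted them for every gene, joined larvae with tail, left out germ-cell and pancreas genes, or rescaled the immediate early list were chosen only after the data were seen. Of 101 alternatives to the main results (89 set beforehand, 12 added), 75 left the result the same, 24 moved it and 2 reversed it. For the 5 platform tests the same means the same sign, whatever the size, for shares and correlations within 1 SD, and for counts within 1.5 times. For named genes and lists, with 164 set beforehand and 1 added, 86 left it the same, 76 moved it and 3 reversed it, where the same means a log2 change smaller than the SD of the 2 platforms' values, which can exceed 1 log2 unit, or for the immediate early count within 1.5 times. For transcripts, length, introns and annotated chains the sign held in every alternative, and leaving out a tissue raised the smallest exact p to 0.125. Open reading frame alternatives (50 codons, 200 codons, multi-exon transcripts, each tissue left out) were not run, since they need the genome. PacBio depth limits the genes that both platforms could call.

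Where values changed, the cause was not tested unless given. The single-exon difference was -29.0 without gene-body entries, whose removal is itself the cause, and ranged from -0.0756 (without muscle) to 2.19 (without brain) when each tissue was left out. At TPM of 1 or more, gene-body entries included, it was 13.7. At that minimum the other differences were -14508 transcripts, -584 nt of length, -97372 introns and 23.4 points of annotated chains. Illumina then held 94.6% of PacBio introns and PacBio 37.0% of Illumina ones. At 4-fold, a looser rule, tissue-enriched genes were 3 in tail, 122 in muscle, 162 in larvae, 302 in brain and 368 in liver. On Illumina alone, which drops a requirement, they were 3 in tail, 94 in muscle, 170 in larvae, 195 in brain and 297 in liver, and 39 genes were higher in tail and 933 in whole larvae. Under TMM scaling 170 were enriched in muscle, 105 in larvae and 35 in brain, 23 were higher in tail and 298 in whole larvae. Larvae and tail as 1 group gave 134. Genes higher in tail were 15 with a pseudocount of 0.1 and 17 at abundance of 1 or more. At 50 TPM or more, a stricter rule, isoform differences were 5 (larvae and muscle), 15 (larvae and brain), 3 (larvae and liver), 11 (muscle and brain), 6 (muscle and liver) and 7 (brain and liver). The vitellogenin median in larvae was -0.0174 under TMM scaling, and the giant gene median in muscle on Illumina 0.30 under TMM scaling and 0.00167 with a pseudocount of 0.1.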

Other observations

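The immediate early list and the genes of this part were chosen only after their values were seen. Of the 7 genes with the symbol HBE1, a beta-type globin, 4 were larval, at 139.5, 269.8, 817 and 117 TPM in larvae and 197, 483, 1317 and 178 TPM in tail on Illumina, with at most 0.146 TPM in adult tissues. The other 3 were adult, and the most abundant (ENSDARG00000089087) was at 291, 862 and 683 TPM in muscle, brain and liver against 0.21 TPM in larvae. The fast myosin gene myhc4 was at 18370 TPM in adult muscle and 92.7 TPM in larvae on Illumina (9571 and 3216 TPM on PacBio), and myhz1.1 at 200.5 TPM in muscle and 3879 TPM in larvae (2436 and 8667 TPM on PacBio), though abundance split among such paralogues is uncertain. The parvalbumin pvalb2 was at 15400 TPM in larvae, 26510 TPM in tail and 2591 TPM in muscle. The kinase gene nme2b.2 was at 74970 TPM in muscle on Illumina, and 1394 TPM on PacBio.

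Of 28 names of the immediate early list 27 were matched, which gave 26 genes, and 17 of them (65.4%) were highest in brain on Illumina, or 13 of 22 outside the enriched genes. The median was 23.9 TPM in brain against 7.23 in larvae, 6.10 in muscle and 0.467 in liver. Under TMM scaling 12 of 26 were highest in brain and 11 in muscle, with medians of 11.3 and 11.8, so that brain did not stand above muscle. The early-response factors egr1, NPAS4, egr4 and FOS led at 678, 249, 241 and 136 TPM. NR4A1, a nuclear receptor, went the other way, at 153 TPM in muscle and 24.5 in brain. On PacBio 9 of 21 were highest in brain and 9 in muscle, and outside the enriched genes 5 of 17 in brain and 9 in muscle. The neuropeptide genes NPY, pdyn and GAL were at 65.5, 62 and 47.6 TPM in brain against 5.24, 6.03 and 8.21 TPM in larvae on Illumina, and at 91.5, 125.4 and 80.4 TPM in brain on PacBio. In liver IGF1, a growth factor, was at 175 TPM and hamp, the iron hormone hepcidin, at 375 TPM.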
